A study of Mus musculus with 6 samples.

How the data were processed

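The data were poly-A selected RNA sequencing libraries from the ventral part of the lumbar spinal cord of 5-week-old C57BL/6 mice, 3 wild-type (WT) and 3 lacking Gdpd5 (Gde2KO). Gdpd5 encodes GDE2, a membrane enzyme that releases proteins from their glycosylphosphatidylinositol (GPI) anchors. Per the submitters' processing notes, reads were checked with FastQC, aligned to the mouse genome build mm10 with TopHat2 2.1.1, assembled with Cufflinks 2.2.1 and compared with Cuffdiff 2.2.1. The version of FastQC is not given in the sources used here. Each deposited file is one library's own Cufflinks assembly, and its FPKM values (fragments scaled to assembled transcript length and library size) with their confidence bounds were made by the authors. The files number their genes separately and name no reference gene. The labels describe all 6 libraries with the same flow cell and lane, so no batch could be tested, and they give no sex.

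Assembled transcripts were matched to GENCODE vM21 on GRCm38, the assembly that mm10 denotes, by exon overlap on the same strand. Transcripts without an assembled strand made up 13.1% to 14.1% of each library and were matched on either strand. They counted towards the level of a gene only at bases without an exon of another gene on the opposite strand. Transcripts with fewer than 200 exonic bases were left out, because Cufflinks gives short models extreme FPKM values. Between 11.8% and 13.1% of the remaining transcripts per library overlapped no annotated gene. Counted bases of a gene were its exonic bases shared with no other gene on its strand and assembled in at least 3 of the 6 libraries. The level of a gene was the FPKM summed at each counted base over the transcripts covering it, averaged over those bases. This departs from the plain sum of a gene's transcripts that had been written down before the data were examined. The files split many genes into pieces whose FPKM values would then be added, and the median robust SD of the log2 difference between 2 libraries, computed without regard to genotype, was 0.191 with the value used and 0.322 with the plain sum. The plain sum was kept as an alternative. A gene with no such transcript in a library was given 0, which can be a failed assembly, so such genes are described as listed at 0, with each library's value and no fold.

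Genes with at least 200 counted bases and a mean FPKM of at least 1 were tested, 12894 in all. Libraries were scaled by median-of-ratios factors, which ran from 0.984 to 1.03. Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1) with an intensity trend and robust variance moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds and log2 differences are therefore on the scale with the pseudocount of 0.1 added, which understates changes of low genes. No exact test is given for single genes, since 3 libraries against 3 cannot give an exact permutation p under 0.10.

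A set of 36 gene lists, holding 819 entries, was fixed before the data were examined, and 5 entries matched no annotated gene. The lists cover the oligodendrocyte lineage, cholesterol synthesis, Wnt targets and Wnt signalling proteins, Notch, the GDE family with glypicans and GPI-anchor proteins, neuron-secreted factors, motor, general, inhibitory, excitatory, dorsal horn and sensory ganglion neurons, synapses, astrocytes, reactive astrocytes, microglia, activated microglia, interferon response, endothelial, mural, meningeal, Schwann, ependymal, skeletal muscle and red blood cells, immediate early genes, stress response, respiratory chain, ribosomal proteins, proliferation, 5' Hox and 3' Hox genes, and sex-linked genes. The 32 lists with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Camera compares a list's genes with the other genes tested. The sex-linked list is given as values only, over all bases assembled in any library.

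Genes within 5 Mb of Gdpd5 were compared with the rest by Fisher's exact test and by camera. Isoforms were matched by exact intron chain, since the files name no reference transcripts. Only the 6198 isoforms assembled in all 6 libraries were kept, so an isoform absent from 1 genotype could not be tested. Of these, 2200 with a mean share of 10% to 90% in genes with a mean FPKM of at least 5 were tested. The test was limma on the log-odds of their share. Named genes followed a fixed rule. It takes Gdpd5, up to 12 genes with the smallest adjusted p in each direction without overlap of the groups, filled up to 8 with genes of at least 1.25-fold that did not pass, up to 3 genes of smallest p per list, a fixed set of cell type and Wnt genes, and the called isoforms and genes near Gdpd5. Some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

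On simulated data made from the real means and spreads, the gene test called 27 of 67 genes changed 1.5-fold, 47 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 3 false calls among 12536 unchanged genes. Camera found a planted list of 20 genes changed 1.25-fold and passed 3% of 200 random lists at an unadjusted p of 0.05. The simulated noise was independent between genes, with no effect shared within a library and no failed assembly. These false rates therefore do not carry over to the real genes and lists. The isoform test called 35 of 100 isoforms whose odds were changed 9-fold, and 0 of 2100 unchanged ones. Alternatives covered the pseudocount, the filter, scaling, variance model, library weights, a replicate block, leaving out each library, the gene-level value, the set test, the window and the isoform filters. Calculations and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read lengths and read totals are not in the files, so absolute depth is unknown. The ratio of assembled depth to FPKM gives relative depth between libraries, and the confidence bounds in the files, which cover counting and assignment error of each library alone, had a median width to each side of 9.10% to 11.0% of the FPKM.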

Results

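Transcript levels were measured by poly-A RNA sequencing in the ventral lumbar spinal cord of 5-week-old mice, in 3 WT and 3 Gde2KO animals, each sequenced as one library. The series asks how GDE2 in neurons bears on Wnt signalling and on the maturation of oligodendrocytes, the myelin-forming cells. Each library held between 31899 and 33791 assembled transcripts. Relative depth, with 1 as the average, was 0.953, 1.04 and 0.916 in WT replicates 1 to 3 and 0.943, 1.018 and 1.13 in Gde2KO replicates 1 to 3. Gde2KO replicate 3 stood apart in its assembly. Of its multi-exon transcripts 56.6% had an annotated intron chain, against 49.6% to 50.03% in the other 5 libraries, and the robust SD of its log2 differences from other libraries was 0.257 to 0.291, against 0.146 to 0.194 between the others. Gde2KO replicate 1 stood apart in its sex-linked genes. It alone held Ddx3y, a gene of chromosome Y, at 21.5 FPKM, and it was the one library with Xist, the RNA of the inactive X chromosome, listed at 0, against 1.21 to 2.58 FPKM elsewhere. Replicate 1 of Gde2KO also had low connective tissue markers, with the collagen gene Col1a1, chosen after its values were seen, at 4.87 FPKM against 12.9 to 18.04 in the other 5 libraries.

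Gdpd5 was low in every Gde2KO library and its exon 11 was nearly absent there. The gene lies on chromosome 7 from 99381414 to 99461877 on the plus strand and reached 5.42, 6.58 and 5.99 FPKM in WT against 1.251, 1.20 and 0.951 in Gde2KO. The mean fell from 6.00 ± 0.577 to 1.14 ± 0.161 (SD, n = 3 each), a fold of 0.202 (95% interval 0.161 to 0.253) with a limma adjusted p of 0.00535. Along the 18 exons of the annotated transcript ENSMUST00000037528.9, exon 11 (chromosome 7, 99451714 to 99451796) averaged 6.16 ± 0.567 FPKM in WT and 0.0232 ± 0.0229 in Gde2KO, or 0.377% of WT. Exons 12 to 17 stood at 26.3% of WT, exons 2 to 6 at 13.4%. All 3 WT libraries held a single assembled transcript with 18 exons, and each Gde2KO library held 2, none of them with all 18. With the plain sum of transcripts, which adds those pieces, the log2 difference was -1.45 with an adjusted p of 0.0790. Over the alternatives that tested Gdpd5 the limma adjusted p ran from 0.00269 to 0.155.

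**Figure D1:**
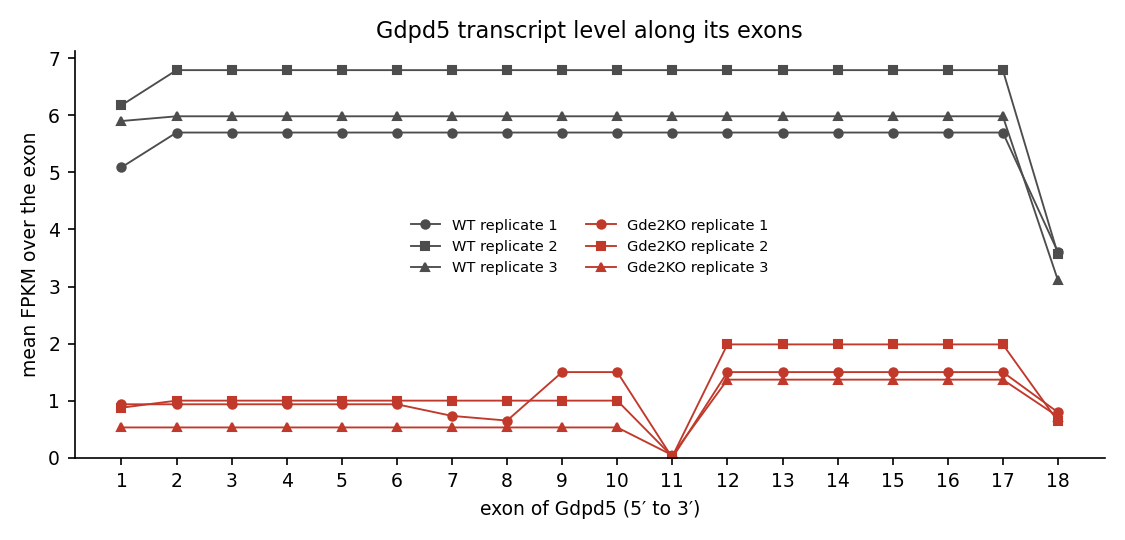
Mean FPKM over each of the 18 exons of Gdpd5, one line per library, WT in grey and Gde2KO in red. WT libraries lie between 5.70 and 6.79 from exon 2 to exon 17, and Gde2KO libraries at or under 1.99, with 0 to 0.0458 at exon 11.

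Between the genotypes few genes differed beyond the spread of the replicates. Of 12894 genes tested, 15 passed, 5 higher and 10 lower in Gde2KO, and in 9 of them every library of one genotype was listed at 0. Myo7a, a motor protein of sensory hair cells that lies on the same chromosome as Gdpd5, fell from 2.65 ± 0.0827 to 0.155 ± 0.0275 FPKM (SD, n = 3 each; limma adjusted p = 0.00604). Nell2, which encodes a secreted neuronal protein, rose from 27.1 ± 0.880 to 55.6 ± 2.86 FPKM, a fold of 2.04 (1.83 to 2.29; adjusted p = 0.00674). Rrm1, a subunit of ribonucleotide reductase, fell from 6.78 ± 0.0377 to 4.14 ± 0.147 (adjusted p = 0.0250), and the chromatin protein gene Phf14 fell from 6.27 ± 0.107 to 1.34 ± 0.311 (adjusted p = 0.0144).

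The assembled transcripts of several of these genes differed in extent between the genotypes. For Nell2 the last exon of the longest assembled transcript held 3920 to 3984 bases in WT and 531 to 601 in Gde2KO. Fragments per gene is a value in which assembled length is no divisor, so longer assembled transcripts can hold more fragments. By it the log2 difference of Nell2 was 0.05 (limma adjusted p = 0.871). Rrm1 showed the opposite, with a last exon of 487 to 492 bases in WT and 5436 to 5604 in Gde2KO, and fragments per gene gave a log2 difference of 0.21 (adjusted p = 0.871). Phf14 kept 36.2% to 44.8% of its counted bases in Gde2KO against 89.9% to 94.6% in WT, and by fragments per gene stood at -1.69 (adjusted p = 0.119). Myo7a stayed low by fragments per gene, at -3.39 (adjusted p = 0.0105), and with the plain sum, at -2.08 (limma adjusted p = 0.0435). Of its counted bases 21.9% to 45.3% were assembled in Gde2KO, against 99.8% to 100% in WT. Unassembled bases add no fragments, so these values cannot separate a lower level from a failed assembly. The longest assembled transcript of Myo7a stood at 0.428 to 0.589 FPKM in Gde2KO, against 2.52 to 2.71 in WT. A failed assembly at an unchanged level would leave assembled pieces near the WT value, so these FPKM values argue against it as the whole account. Calls also ended when single libraries were left out. Nell2 had an adjusted p of 0.0610 without WT replicate 1 and 0.0571 without WT replicate 3. Myo7a lost its call without WT replicates 1, 2 or 3 (0.0982 to 0.119), Phf14 without any 1 WT replicate or Gde2KO replicate 3 (0.0694 to 0.0897), and Rrm1 without any 1 of the 6 libraries (0.0594 to 0.135).

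Among the genes listed at 0 in one genotype, 6 were at 0 in Gde2KO. Ppil3, a peptidyl-prolyl isomerase, stood at 16.1, 15.8 and 17.6 FPKM in WT, Cd200r3, a receptor of immune cells, at 17.2, 12.6 and 15.5, and Fbxw16, an F-box protein gene, at 3.36, 4.94 and 3.51. Mppe1, a phosphodiesterase, was listed at 0 in WT and at 6.38, 8.84 and 10.4 in Gde2KO, and Ccdc51 at 3.53, 3.61 and 3.87. Their limma adjusted p values ran from 3.00e-05 for Ppil3 to 0.00604 for Fbxw16. Of these 9 genes, 8 had a transcript of the other strand or one under 200 bases over the same exons in a library listed at 0, against 63 of the 108 other genes at 0 in exactly 3 libraries (58.3%; Fisher's exact p = 0.0868, two-sided). Ccdc51 lost its call without any 1 Gde2KO replicate (limma adjusted p of 0.183 to 0.284) and Fbxw16 without any 1 WT replicate (0.135 to 0.238). In Cd200r3, Gde2KO replicates 1 and 2 each held such a short transcript. The 5 remaining called genes are unnamed models, given here after their values were seen. Gm11491, Gm26722 and 9230104M06Rik were listed at 0 in Gde2KO and Gm4462 in WT, while 2410002F23Rik was higher in Gde2KO (16.6 against 0.803 FPKM) with 1.65% to 5.65% of its counted bases assembled in WT. By fragments per gene the log2 difference of 2410002F23Rik was 2.17 (adjusted p = 0.00319), while its transcripts summed to 15.3, 17.3 and 16.6 FPKM in Gde2KO and to 20.5, 21.5 and 16.8 in WT.

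Further genes had groups that did not overlap but did not pass. Higher values in Gde2KO were seen for Mrpl48-ps (log2 difference 1.84), Olfml1 (1.38), Ndufaf5 (1.27), Id1 (0.53), an inhibitor of neural differentiation, and the endothelial factor Sox18 (0.52), with adjusted p values from 0.0978 for Mrpl48-ps to 0.249 for Id1. Olfml1 lies on chromosome 7, 8.11 Mb from Gdpd5. Smim10l2a was lower by a log2 difference of -1.03 (adjusted p = 0.0813). Ndufaf5 and Smim10l2a had near-equal values by fragments per gene, at -0.02 and 0.14. Groups did not overlap for 10.8% of genes, where chance gives 10%, and 505 genes (3.92%) had an unadjusted p under 0.05. The median 95% interval reached 0.28 on the log2 scale to each side. Called genes numbered 4 with genes listed at 0 treated as missing, 1 with a mean FPKM of at least 5, and 23, 25 and 23 without Gde2KO replicate 2, Gde2KO replicate 3 and WT replicate 2. The balance of directions turned with the genotype of the library left out. It was 2 higher and 17 lower, 5 and 18, and 4 and 21 without Gde2KO replicates 1, 2 and 3, and 7 higher and 3 lower, 20 and 3, and 13 and 3 without WT replicates 1, 2 and 3.

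Oligodendrocyte genes were near-equal in the genotypes at the level of the lineage. Of 42 measured genes of mature oligodendrocytes and myelin, 21 were higher and 21 lower, with a median log2 difference of 0.00 (camera adjusted p = 0.985; with an estimated correlation, adjusted p = 0.995). Direction of this list turned in 9 of 22 alternatives, quantile normalization among them (adjusted p = 0.829), and it passed in none. The myelin adhesion gene Mag averaged 498 ± 41.9 FPKM in WT and 509 ± 7.83 in Gde2KO (SD, n = 3 each), and the maturation factor Myrf 55.7 ± 7.60 and 56.0 ± 6.03. Folds of Mog (1.15, 95% interval 0.906 to 1.47) and Cnp (0.865, 0.582 to 1.28) had intervals that included 1. Opalin, a gene of late maturation, was at 88.1 ± 5.54 in WT and 75.5 ± 3.67 in Gde2KO, with no overlap and an adjusted p of 0.883 that did not pass. Gsn stood at a fold of 1.22 and Ninj2 at 0.856. Mobp was at 255, 476 and 1388 FPKM in WT and at 1418, 1510 and 1363 in Gde2KO, so its difference lay within the spread of WT. Mbp, the myelin basic protein gene, could not be measured. None of the exonic bases of Mbp alone was assembled in at least 3 of the 6 libraries by transcripts of at least 200 bases.

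Earlier stages gave the same picture. Newly formed oligodendrocyte genes were higher for 10 and lower for 10 of 20 measured, with a median log2 difference of 0.04, a mean of -0.02 and a camera direction of higher (adjusted p = 0.977). Enpp6 had a fold of 1.16 (0.947 to 1.41), Gpr17 of 1.16 (0.885 to 1.52) and Bcas1 of 0.905 (0.737 to 1.11). Plekhg1 and Fam107b stood at 0.892 and 0.789. Precursor genes were higher for 9 and lower for 13 of 22 (median log2 difference -0.04, adjusted p = 0.799), with the growth factor receptor Pdgfra at a fold of 1.14 (0.934 to 1.40), Cspg4 at 1.03 (0.888 to 1.20), Olig2 at 0.957 (0.785 to 1.17), Sox10 at 0.825 (0.608 to 1.12), Tnr at 1.29 and Vcan at 1.16. The phosphatase receptor Ptprz1 had a fold of 1.05 (0.904 to 1.22). Cholesterol synthesis genes, needed for myelin membrane, were higher for 9 and lower for 15 of 24 (median -0.02, adjusted p = 0.799), with Fdps at a fold of 0.879 and Insig1 at 0.916. Neuron-secreted and axonal factors that act on oligodendrocytes were higher for 12 and lower for 13 of 25 (adjusted p = 0.570), with Nptx1 at 0.886, L1cam at 0.920 and Cxcl12 at 0.785.

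**Figure D2:**
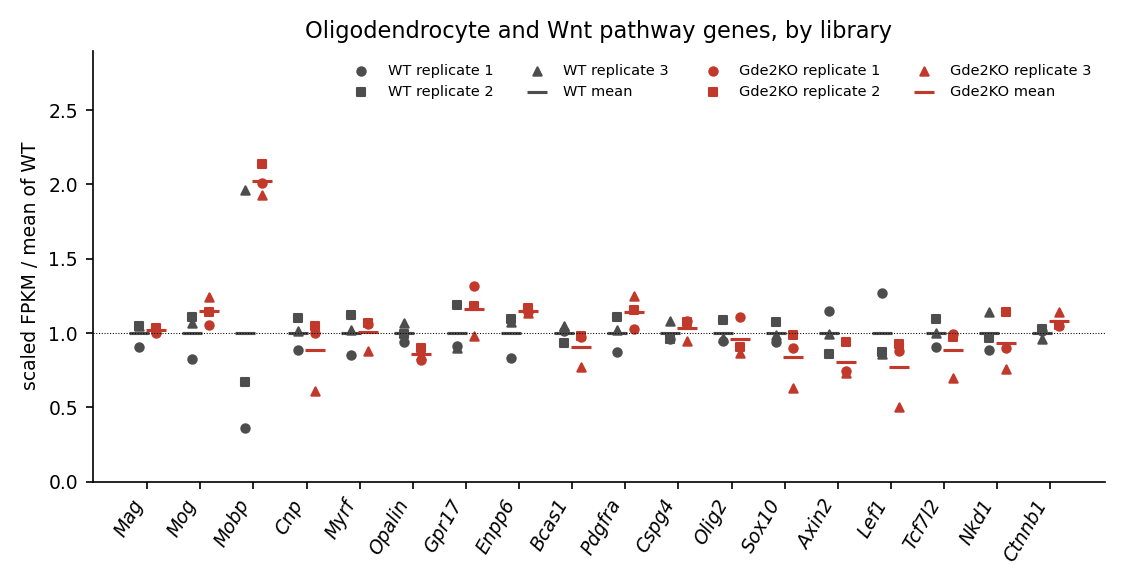
FPKM of oligodendrocyte lineage and Wnt pathway genes in each library, divided by the mean of the 3 WT libraries, with WT in grey and Gde2KO in red, symbols for replicates and bars for group means. Mobp spans 255 to 1388 FPKM within WT, and the groups overlap for most of the genes drawn.

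Canonical Wnt target genes were lower as a group in Gde2KO. Of 19 measured, 14 were lower and 5 higher, with a median log2 difference of -0.19 and a mean of -0.17 (camera adjusted p = 0.00232), and 3 had an unadjusted p under 0.05. With an estimated correlation the list did not pass (adjusted p = 0.647). Bambi, a decoy receptor, had 3.68 ± 0.364 FPKM in WT and 2.93 ± 0.0792 in Gde2KO, Tnfrsf19 12.1 ± 0.411 and 10.8 ± 0.431, and the glial factor Sox9 7.39 ± 0.909 and 5.39 ± 1.29 (SD, n = 3 each). Axin2, a feedback inhibitor of the pathway, had a fold of 0.814 (0.630 to 1.05), Lef1 of 0.766 (0.476 to 1.23) and Nkd1 of 0.926 (0.687 to 1.248). None of these genes passed alone. The list passed without each library in turn, with adjusted p values of 0.00194 to 0.0436, and did not pass with the plain sum of transcripts (adjusted p = 0.656). Over all alternatives the adjusted p ran from 0.00133 to 0.656, under 0.05 in 19 of 22. All of those 19 used camera with the preset correlation. The plain sum, the estimated correlation and another set test, fry (adjusted p = 0.424), did not pass.

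Wnt ligands, receptors and signalling proteins were also lower as a group, 30 of 44 measured, with a median log2 difference of -0.06 (adjusted p = 0.0453; with an estimated correlation, adjusted p = 0.647). Bcl9, a coactivator of beta-catenin, had a fold of 0.736, Dvl2 of 0.791 and the receptor Fzd10 of 0.716. Ctnnb1, which encodes beta-catenin, stood at 1.08 (0.959 to 1.22) and the transcription factor Tcf7l2 at 0.888 (0.669 to 1.18). This list lost its call without Gde2KO replicate 1 (0.0737), Gde2KO replicate 3 (0.217), WT replicate 2 (0.104) or WT replicate 3 (0.0543), and with the plain sum (0.369). Notch pathway genes split into 8 higher and 10 lower, with a median log2 difference of -0.08, a mean of 0.01 and a camera direction of lower (adjusted p = 0.478). Hes1, a Notch target that holds back differentiation, had the smallest p of that list, with 2.44 ± 0.304 FPKM in WT and 3.73 ± 0.354 in Gde2KO, and did not pass (adjusted p = 0.796), and Notch1 and Maml1 stood at folds of 0.850 and 0.886. Genes of the GDE family, glypicans and GPI-anchor proteins were higher for 11 and lower for 10 of 21, with a median of 0.00, a mean of -0.00, a camera direction of higher and an adjusted p of 0.799, and included Adam10 (fold 1.09), Gpc1 (1.10) and Pgap1 (1.14).

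By camera, motor neuron genes were slightly higher as a group and synapse genes slightly lower, but not in every library. Of 25 motor neuron genes 16 were higher (median log2 difference 0.11, adjusted p = 0.0493; with an estimated correlation, adjusted p = 0.647), with the intermediate filament gene Prph at a fold of 1.24, Stk32a at 1.16 and Aldh1a2 at 0.593. The acetylcholine genes Chat and Slc18a3 had folds of 0.984 (0.760 to 1.27) and 1.19 (0.817 to 1.73), and Isl1 of 1.10 (0.834 to 1.45). Synapse genes were lower for 20 of 28 (median -0.09, adjusted p = 0.0453; with an estimated correlation, adjusted p = 0.806), with Pclo at 0.844, Camk2b at 0.901 and Gria3 at 0.814. On the log2 scale from WT, synapse genes averaged 0.06, -0.10 and -0.21 in Gde2KO replicates 1 to 3, in the same order as superficial dorsal horn genes (0.32, -0.09 and -0.45), and motor neuron genes 0.13, 0.01 and 0.10. The motor neuron call was lost without Gde2KO replicate 1 (0.398), Gde2KO replicate 3 (0.120) or WT replicate 1 (0.342), and the synapse call without Gde2KO replicate 2 (0.260), Gde2KO replicate 3 (0.518) or WT replicate 1 (0.342). General neuron genes did not pass (22 measured, median -0.08, adjusted p = 0.355), with Snap25 at 0.993 (0.872 to 1.13), Eno2 at 1.20, Uchl1 at 1.34 and Map2 at 0.905. Inhibitory neuron genes did not pass either (14 measured, median -0.10, adjusted p = 0.258), with Nos1 at 0.869, Pax2 at 0.807 and Pvalb at 0.860. Only 3 excitatory neuron genes were measured, too few to test, with Slc17a6 at 0.996 and Shox2 at 0.625.

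Astrocyte and microglia lists showed no group difference that passed, and interferon response genes were lower. Astrocyte genes were higher for 12 of 20 (median log2 difference 0.02, mean -0.01, camera direction higher, adjusted p = 0.799), with Gfap at a fold of 1.01 (0.818 to 1.253), Aldoc at 0.710 and Aldh1l1 at 1.14. Reactive astrocyte genes had a median of -0.08 over 19 measured (adjusted p = 0.0598), with Cp at 0.783, S1pr3 at 0.880 and Lcn2 at 0.819. That list passed in 6 of 22 alternatives. Microglia genes were higher for 12 of 22 (median 0.02, mean -0.01, camera direction higher, adjusted p = 0.799), with Aif1 at 0.980 (0.810 to 1.19), Csf1r at 1.09, Tmem119 at 1.11 and Cd68 at 0.794. Activated microglia genes were lower for 10 of 16 (median -0.05, adjusted p = 0.366), with B2m at 0.595, H2-Ab1 at 0.693 and H2-K1 at 0.906. Interferon response genes were lower for 14 of 16 (median -0.23, adjusted p = 0.00375; with an estimated correlation, adjusted p = 0.647), with Ifitm3 at 0.622, Oasl2 at 0.776 and Stat2 at 0.802. On the log2 scale from WT, interferon genes averaged -0.17, -0.29 and -0.25 in Gde2KO replicates 1 to 3. In WT replicates 1 to 3 they averaged 0.30, -0.05 and -0.26. The interferon call was lost without WT replicate 1 (camera adjusted p of 0.342) or Gde2KO replicate 2 (0.0627), and with the plain sum (0.131).

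Genes of the meninges and of the ependyma, the lining of the central canal, were lower as groups. All 16 measured meningeal and fibroblast genes were lower (median log2 difference -0.38, adjusted p = 0.00232; with an estimated correlation, adjusted p = 0.647), with Slc6a13 at a fold of 0.608, Fn1 at 0.820 and Fmod at 0.626. On average they stood at -1.02 on the log2 scale from WT in Gde2KO replicate 1, -0.07 in replicate 2 and -0.08 in replicate 3, and the call was lost without Gde2KO replicate 1 (0.251). Ependymal genes were lower for 9 of 10 (median -0.28, mean -0.64, adjusted p = 0.00296; with an estimated correlation, adjusted p = 0.641), with Fam183b at 0.739 and Dynlrb2 at 0.703. Rarres2 was listed at 0 in Gde2KO replicates 1 and 2, at 12.2 FPKM in replicate 3 and at 10.3 to 12.8 in WT. With the plain sum both lists missed the threshold (0.116 and 0.0798). Endothelial genes were lower for 16 of 20 (median -0.10, adjusted p = 0.0598), with Kdr at 0.662, Eng at 0.792 and Emcn at 0.792. Mural cell genes were lower for 7 of 13 (median -0.04, adjusted p = 0.242), with Vtn at 0.811, Ndufa4l2 at 0.732 and Pdgfrb at 0.735. Red blood cell genes were lower for 4 of 5 (median -0.13, adjusted p = 0.241), with Alas2 at 0.751 and Bpgm at 0.943.

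Immediate early genes, which neurons and vessels switch on within minutes of activity or stress, were lower as a group, 12 of 14 measured, with a median log2 difference of -0.42 (adjusted p = 0.00170; with an estimated correlation, adjusted p = 0.641). Btg2 stood at a fold of 0.604, Dusp1 at 0.722 and Ccn1 at 0.770, and 5 of the 14 had an unadjusted p under 0.05. The list's average was -0.67 in Gde2KO replicate 1, -0.12 in replicate 2 and -0.50 in replicate 3, and it passed without each library in turn. Respiratory chain genes were slightly higher, 24 of 29 (median 0.08, adjusted p = 0.0155; with an estimated correlation, adjusted p = 0.679), with Sdhb at 1.14, Cox6c at 1.23 and Ndufb9 at 0.670. That call was lost without Gde2KO replicate 3 (0.406), WT replicate 2 (0.155) or Gde2KO replicate 2 (0.0548). Genes of the stress response (median 0.05, adjusted p = 0.287), with Pdia4 at 1.13, Hspa5 at 1.17 and Gadd45a at 0.881, ribosomal proteins (median 0.01, mean -0.04, camera direction lower, adjusted p = 0.799), with Rpl8 at 0.726, Rps27 at 0.667 and Rpl14 at 1.29, and proliferation (median -0.11, adjusted p = 0.287), with Mcm2 at 0.874, Mcm3 at 0.874 and Mcm6 at 0.928, did not pass. Over the 36 lists, 0 genes passed limma over all genes tested and 0 passed adjusted over the list alone, with 0 to 5 genes per list at an unadjusted p under 0.05. Camera passed 10 lists, 0 of them with an estimated correlation and 1 with the plain sum of transcripts.

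**Figure D3:**
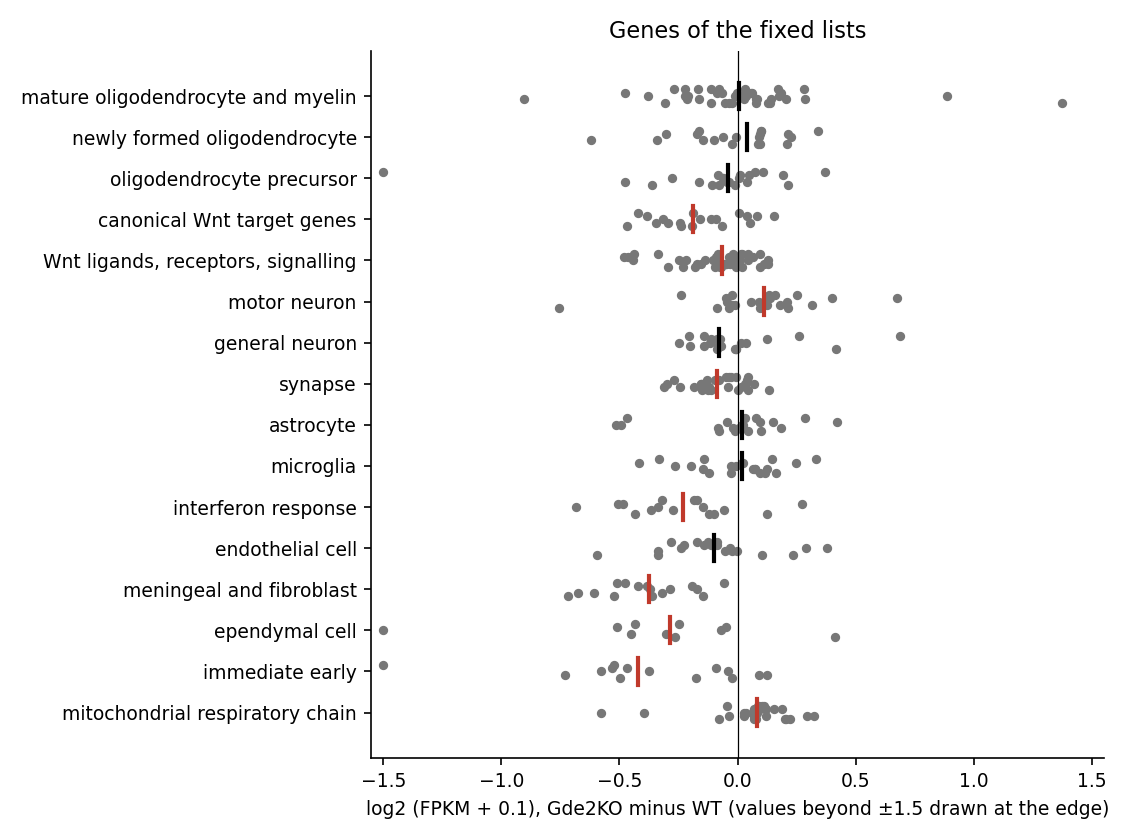
Log2 difference, Gde2KO minus WT, of each measured gene in 16 of the fixed lists, with the list median as a bar, red where camera with the preset correlation gave an adjusted p under 0.05 and black elsewhere. Meningeal genes lie left of 0 throughout, mature oligodendrocyte genes lie evenly around it, and 3 genes beyond 1.5 in size are drawn at the edge.

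Genes around Gdpd5 on chromosome 7 differed more often than genes elsewhere. The question was whether neighbours of the targeted gene stood apart, as can happen when chromosome from another strain stays beside a targeted gene. Within 5 Mb, 13 of 71 genes (18.3%) had an unadjusted p under 0.05, 11 of them lower and 2 higher, against 3.83% elsewhere (Fisher's exact p = 3.10e-06, two-sided), and as a group the 71 were lower (camera p = 0.00253). By fragments per gene the share was 18 of 69 (26.1%, against 3.50% elsewhere), 12 lower and 6 higher. Rrm1 was counted among the higher ones there, with a log2 difference of 0.21, the reverse of its direction above. With the plain sum the share was 10 of 80 (12.5%, against 3.79% elsewhere, Fisher's exact p = 0.000937), with 8 of the 13 genes still under 0.05. Of these genes 2 passed alone, Myo7a (chromosome 7, 98051060 to 98119524, 1.26 Mb away) and Rrm1 (102441695 to 102469771, 2.98 Mb away), a share of 2.82% against 0.0936% elsewhere (Fisher's exact p = 0.00261). Others are named here after their values were seen. Slco2b1, an organic anion transporter 0.196 Mb away, had 6.29 FPKM in WT and 4.45 in Gde2KO, Serpinh1, a collagen chaperone 0.0282 Mb away, 17.8 and 13.1, and Ndufc2, a respiratory chain subunit 1.97 Mb away, 148 and 102. Nars2, an asparagine tRNA synthetase gene, was the other way, at 2.43 and 3.62. The share was 15% of 20 genes within 1 Mb, 19.6% of 51 genes at 1 to 5 Mb, 8.70% of 46 genes at 5 to 10 Mb (Fisher's exact p = 0.0984), 9.17% of 120 genes at 10 to 20 Mb (0.00668) and 4.38% of 730 genes more than 20 Mb away. Counted by calls, 0 genes passed within 1 Mb, and the 2 calls became 1, Myo7a, without Gde2KO replicate 2 or Gde2KO replicate 3 and 0 without any 1 WT replicate. Without Gde2KO replicate 1 the 2 calls were Myo7a and, in place of Rrm1, Lrrc51 (adjusted p = 0.0176), which was at 2.85, 0 and 0 FPKM in Gde2KO and 2.89, 2.76 and 3.57 in WT and did not pass with all libraries.

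**Figure D4:**
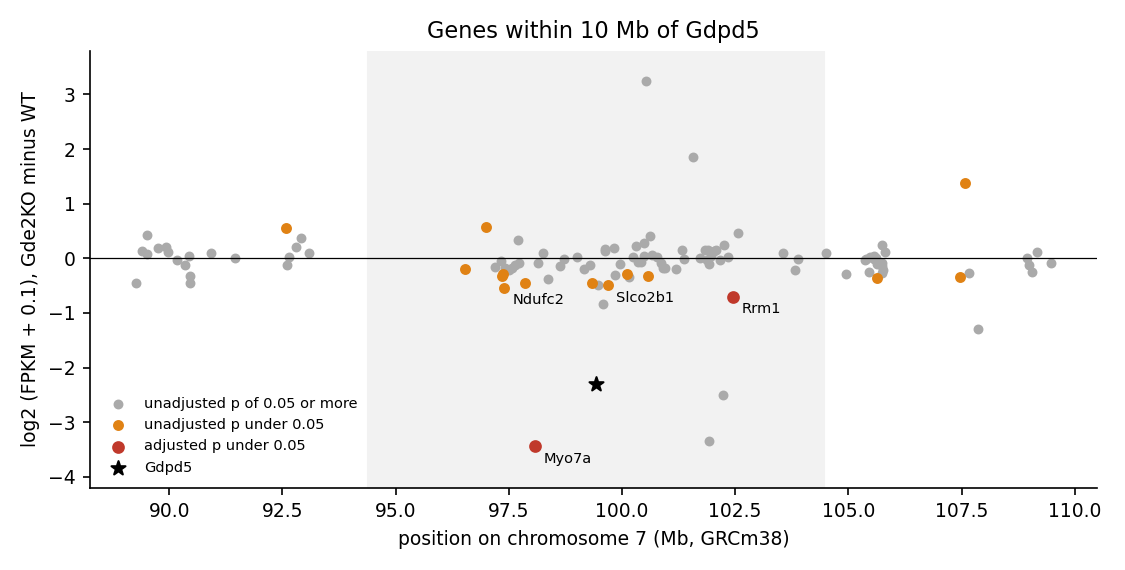
Log2 difference, Gde2KO minus WT, against position on chromosome 7 in Mb for tested genes within 10 Mb of Gdpd5, with the 5 Mb window shaded. Genes listed at 0 in one whole genotype are not drawn; Myo7a and Rrm1 (red) passed, and of the 13 genes in the window at an unadjusted p under 0.05, 11 were lower, against 12 of 18 by fragments per gene.

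Among isoforms assembled in all 6 libraries, few could be said to differ in share between the genotypes. The test called 35 of 100 simulated isoforms with odds changed 9-fold, and isoforms absent from 1 genotype were not tested. Of 2200 annotated isoforms in 1847 genes, 1 passed, the isoform ENSMUST00000059026.9 of Abi3, an actin regulator of microglia. It made up 8.54%, 5.34% and 3.08% of Abi3 in WT and 100% in each Gde2KO library (limma adjusted p = 0.00155). In each WT library Abi3 also held a separate single-exon piece of 1872 to 3005 bases over its last exon, and in WT replicate 3 a further transcript. In Gde2KO the last exon, of 2444 to 2852 bases, was part of 1 transcript with 8 exons. The piece in WT adds to the gene's total, so these shares do not measure isoform use alone. Abi3 as a whole had a fold of 1.03. Both tested isoforms of Cnp had near-equal shares, with 48.3% ± 3.24 of Cnp in WT and 49.1% ± 0.640 in Gde2KO for ENSMUST00000103120.4 (SD, n = 3 each). Large differences that did not pass, named after their values were seen, were those of isoforms of Hoxc8 (100% in WT, 47.1% in Gde2KO), Tmem132e (100% and 43.8%), Ube2e2 (31.3% and 78.2%), Dcp2 (50.8% and 100%) and Frs3 (50.5% and 100%), each with an adjusted p of 0.215. In all, 93 isoforms (4.23%) had an unadjusted p under 0.05. The count of called isoforms was 0 without WT replicate 3, 2 without Gde2KO replicate 1 or WT replicate 1, and 3 without Gde2KO replicate 3.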

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

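Every test in this part was chosen after the result was seen, except that of the Wnt list against 3 cell type lists and the undecided test named below.

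Genes of chromosome Y, which no comparison used, were found in 1 library. In Gde2KO replicate 1, Ddx3y stood at 21.5 FPKM, Eif2s3y at 6.60, Uty at 1.999 and Kdm5d at 1.66, against 0 in the other 5 libraries, WT included. Xist was at 0 in that library alone, so sex-linked transcripts were not balanced between the genotypes. The labels give no sex for any animal, and no fit included it. In this library an effect of sex cannot be told apart from other differences, such as the low average of its meningeal genes (-1.02).

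Most of the 15 called genes were listed at 0 in one genotype or differed in assembled length. If assembly dropped genes without regard to genotype, about 10% of the 117 genes at 0 in exactly 3 libraries would be at 0 in the 3 of one genotype, and 10.3% were, while other splits of the libraries reached 16.2%. That is 12 genes, under the 14.2 that would be needed if the 9 called ones were real losses or gains on top of 11.7 by chance, which argues against a true change as the account of all 9. Nell2 and Rrm1 may owe their calls to the length of the assembled last exon, since fragments per gene left them at 0.05 and 0.21 on the log2 scale. Myo7a kept its difference by fragments per gene (-3.39). Only 21.9% to 45.3% of its counted bases were assembled in Gde2KO. Its longest assembled transcript stood at 0.428 to 0.589 FPKM there, against 2.52 to 2.71 in WT. That argues against a failed assembly at an unchanged level as the whole account. The size of its fall stays open.

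A flanking stretch kept from a donor strain could account for the higher share near Gdpd5. The share reached 19.6% at 1 to 5 Mb and lay above the rest of the genome on both sides, at 33.3% and 10.6%. The 10.6% rests on 5 of 47 genes (Fisher's exact p = 0.0333). Those 5 include Rrm1, whose call may come from assembled length, and Gm35082, listed at 0 in WT. Support from that side is therefore weak. An effect of the targeted allele limited to within 1 Mb is argued against by Fisher's exact test of the genes at 1 to 5 Mb (p = 2.13e-05). Among the genes under 0.05 there, Nars2, Pak1, Myo7a, Gm35082 and Rrm1 had under 80% of their counted bases assembled in some library. The test was not repeated without such genes, so it alone cannot exclude that effect. Incomplete transcripts are argued against as the whole account by genes with at least 80% of their bases assembled in every library. Among these the share was 14.8%, against 3.64% elsewhere (Fisher's exact p = 0.000767). That filter looks at counted bases alone and cannot see transcripts that run past the gene, so over-long transcripts stay open. By fragments per gene the share was 26.1%, but that value itself changes with assembled length and cannot decide. An earlier test of incomplete or over-long transcripts, written before its result was seen, was undecided and was replaced. In it, 8 of the 13 genes had at least 80% of their bases assembled in every library. A wider regional effect of the allele was not tested, and no sequence variants were used.

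For the lower Wnt target list, fewer meningeal, ependymal or endothelial cells in the Gde2KO tissue cannot be told apart from an effect of genotype, because 6 libraries leave wide intervals. With the library mean of each list as a covariate 100%, 213% and 73.4% of the mean difference was left, and the interval with the endothelial list ran from -0.43 to 0.18 on the log2 scale. The 213% rests on Rarres2, listed at 0 in 2 Gde2KO libraries, and without that gene, a fit chosen after the result was seen, 67.6% was left (interval -0.43 to 0.20). The median of the Wnt list was then -0.04, against -0.19 without a covariate, with an unadjusted camera p of 0.173. Correlation among its genes could account for the call, since with an estimated correlation of 0.102 the adjusted p was 0.647. The choice of the gene-level value stays open too, with the list missing the threshold with the plain sum (0.656) and passing with the other 3 ways of making the value, and so does lower Wnt signalling in Gde2KO.

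The 10 possible splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. The real split gave 15 called genes and the highest of the others 23, with 4 splits reaching 15 or more. For lists the real split gave 10 and the highest other 11, with 3 splits reaching 10 or more. Near Gdpd5 it gave 2 called genes and the others at most 0, so that 1 split, the real one, reached 2. For isoforms the real count was 1 and the highest other 3, with 3 splits reaching 1 or more. Camera with the preset correlation gave the Wnt target list an unadjusted p of 0.000217 in the real split, the lowest of all. Splits that mix the genotypes also gave 0.00540, 0.0251 and 0.0256, and the remaining ones over 0.05.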

How the results depend on the processing

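Of the alternatives named here, the plain sum, the other ways of making the gene-level value, genes at 0 treated as missing and genes with at least 50% of their bases assembled were chosen after the data were seen. Gdpd5 kept its direction in the 20 alternatives that tested it and its call in 18 of them. With a mean FPKM of at least 5 it was not tested. Leave-one-out values were -2.38 to -2.20 on the log2 scale. The value was -1.45 (limma adjusted p = 0.0790) with the plain sum and -2.31 (0.155) with the replicate block. Called genes numbered 4 with a pseudocount of 0.01, 1 with a mean FPKM of at least 5, 4 with genes at 0 treated as missing, 2 with only genes at least 50% assembled in every library, and 10 to 25 when 1 library was left out. Near Gdpd5 the calls were 0 with a pseudocount of 0.01 and with a mean FPKM of at least 5. They were also 0 with genes at least 50% assembled and within 1 Mb. There was 1 call with quantile normalization (Rrm1), with the plain sum (Myo7a) and with genes at 0 as missing (Myo7a). The calls were 0 to 2 when 1 library was left out. The most was 3, with Gm35082 added, without a filter on low values, with library weights, or without intensity trend and robust moderation. Called lists numbered 5 with a mean FPKM of at least 5 and with library weights, 1 with the plain sum, 0 with an estimated correlation and 0 with fry, and 5 to 12 when 1 library was left out. Called isoforms numbered 0 to 3 when 1 library was left out. Rrm1 turned to 0.21 with fragments per gene. Fewer genes tested or fewer libraries explain some of these shifts by construction; otherwise the cause was not tested. Replicate numbers did not pair the libraries (correlations of same-numbered deviations of 0.0107, 0.0357 and -0.0671). With the replicate block 2 genes were called, 0 near Gdpd5 and 0 isoforms, and the 10 called lists were among 12. Among single genes, 2710 values kept direction and side of the threshold, 47 lost the threshold, 7 gained it and 57 changed sign without passing either time; among lists, 560 kept both, 71 lost it, 12 gained it and 56 changed sign without passing either time. Lists were not run without the intensity trend or with genes at 0 as missing. A 2-fold change was called for 70.1% of simulated genes, so smaller changes can be missed at this number of animals.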

Other observations

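Genes of axial level and dissection were examined by the fixed lists. All 10 measured 5' Hox genes, which mark caudal levels of the cord, were lower in Gde2KO (median log2 difference -0.22, camera adjusted p = 0.0493). With an estimated correlation the camera adjusted p was 0.647. Hoxa9 stood at a fold of 0.870, Hoxc10 at 0.839 and Hoxc11 at 0.735. The call was lost without Gde2KO replicate 2 (0.128), Gde2KO replicate 3 (0.264) or WT replicate 1 (0.342). The 3' Hox genes had a median of -0.09 over 17 measured and did not pass (adjusted p = 0.799), with Hoxc8 at 1.17 and Hoxb5 at 1.20, while Hoxb3 was at 2.35, 0 and 0.0999 FPKM in Gde2KO and at 2.11 to 2.47 in WT. Superficial dorsal horn genes, which a ventral dissection should largely leave out, had a median of -0.03 over 15 measured (adjusted p = 0.799), with Tac1 at 0.760, Npy at 0.547 and Calb2 at 1.13. On average that list stood at 0.32 on the log2 scale from WT in Gde2KO replicate 1, -0.09 in replicate 2 and -0.45 in replicate 3, and within WT between -0.08 and 0.11.

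Schwann cell genes, 10 measured, had a median log2 difference of -0.11 and a mean of -0.09 with a camera direction of higher (adjusted p = 0.981), and this direction turned in 11 of 22 alternatives, quantile normalization among them. Without Gde2KO replicate 1 the list was higher and passed (adjusted p = 0.0252). Their average stood at -0.999 in Gde2KO replicate 1, 0.41 in replicate 2 and 0.31 in replicate 3, and within WT between -0.30 and 0.41. Cdh19 had a fold of 1.24, Pmp22 of 0.733 and Mlip of 1.246. Only 1 of 17 sensory ganglion genes was measured, Isl1, which motor neurons also express, and 2 of 15 skeletal muscle genes, Mylpf at 0.827 and Casq1 at 0.943. Outside annotated genes, 2536 assembled loci reached 1 FPKM in some library. Of the 300 found in exactly 3 libraries, 8 were in the 3 Gde2KO libraries and 24 in the 3 WT libraries, where chance gives 15 each way.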
